A study of Homo sapiens with 12 samples.

How the data were processed

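Gene expression was measured with Affymetrix whole-transcript gene arrays in MCF7/ADR cells, which the labels give as a breast cell line. Per the labels, cells were left untreated or were exposed for 2 days to 20 mM MC70, 20 mM MC18 or 25 nM PB28. Each of the 4 groups held 3 biological replicates, 12 arrays in all. Cells were pelleted, total RNA was extracted with a column kit, and fragmented, biotin-labelled sense-strand target was prepared with a whole-transcript labelling assay.

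The deposited table holds log2 intensities, 1 value per probe set and array, for 32321 probe sets. Per the submitters' processing notes the authors made these values with RMA, which corrects background, makes the arrays' distributions alike by quantile normalization and summarises the probes of each set, using the affy package. The versions and the chip definition are not given in the sources used here. Array medians lay between 6.11 and 6.17, the lowest value was 1.33 and the highest 14.26, so the values were taken as log2 and were not normalized again. Arrays give no read depth, and the number of arrays limits the precision.

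The probe table gave 1 gene symbol to 19158 probe sets, several to 1388 and none to 11775. The main tests used the probe sets with 1 symbol and, for the 637 genes with more than 1 such set, the set with the highest mean over all arrays, which left 18404 genes. Of these, 18376 had an Entrez identifier that matched the GRCh38.p14 gene table, which was used for names only. No gene was removed for low signal. The comparisons, tests, gene lists, the rule for the genes to be named and, but for 1, the alternative settings were fixed before the data were examined.

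Groups were compared in R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted to all 12 arrays, without covariates, and moderated with eBayes. The 6 pairs of groups were tested two-sided, with p values adjusted by the Benjamini-Hochberg method over all 18404 genes in each comparison and a threshold of 0.05, without a minimum fold. Intervals are 95% intervals of the fitted difference, without correction for the number of genes. Errors of group means are SD over 3 arrays, and errors of log2 changes are standard errors (SE) of the fitted contrast. In simulations made by adding changes to 200 of 18404 genes, 72.6% of genes changed by 0.5 on the log2 scale were recovered, 98.6% of those changed by 1, and 0.1% of those changed by 0.25. Without an added change 0.05 genes were called on average over 20 simulations. The simulated genes varied independently of each other and changed in MC70 only, so these rates do not carry over to comparisons with more changed genes.

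Of 40 gene lists, 39 had at least 5 measured genes, and 914 of the 1055 members written were measured. The list of mitochondrially encoded genes had no measured member and was not used here. Lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 39 lists. Camera with an estimated correlation is given beside each list described. For list members, the count past the threshold over all genes and the count adjusted over the list alone are given. Histone, metallothionein and ribosomal protein genes resemble each other in sequence, so that probes can be shared between members and the identity of the single member is uncertain.

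The named genes are, for each treatment against untreated cells and for MC70 against MC18, among the 10 largest rises and 10 largest falls past the threshold whose 3 arrays all lay beyond the 3 arrays of the other group. Against PB28 the number is 5 each way. Where no gene passed, the 5 smallest p values each way were taken and are said not to pass. The multidrug transporter genes ABCB1, ABCC1 and ABCG2 and the sigma receptor gene TMEM97 were always included, and SIGMAR1 was not analysed here. From each list described, up to 4 members with the lowest adjusted p were eligible. Other members are named where a count of 5 or fewer, an opposite direction or a difference singled them out, and these were chosen after their values were seen.

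Alternatives covered the replicate number as a block, removal of the lowest 30% of genes by mean signal, quantile normalization of the values again, centring on array medians, the mean of all probe sets of a gene, all probe sets, and a fit to only the 2 groups compared. They also covered an intensity trend with robust moderation, array quality weights, a minimum of 1.5-fold, camera with an estimated correlation, limma's fry, and each array left out in turn. With 1 array left out, a group kept 2 arrays. After the data were seen, a fit without the pair of arrays that stood apart on the second principal component, MC18 replicate 3 and PB28 replicate 1, was added, and the members of each described list past the threshold were counted with each array left out. Each comparison was repeated over the 10 splits of its 6 arrays, and the test across all groups over 100 drawn splits of the 12 arrays.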

Results

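Gene expression was profiled on 12 arrays from MCF7/ADR cells, a line of this name being known as doxorubicin-selected and multidrug-resistant. There were 4 groups of 3 biological replicates: untreated cells, cells given 20 mM MC70, cells given 20 mM MC18 and cells given 25 nM PB28, each compound for 2 days. The doses and their units are printed as the labels give them, and the mM unit could not be checked from the arrays. The series concerns MC70 as an inhibitor of multidrug transporters, its anticancer behaviour and the mechanisms behind it, in connection with doxorubicin. PB28 is known as a sigma receptor ligand. The 3 arrays of each group limit the precision of every value below.

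On principal components of the 18404 genes, the first component carried 24.1% of the variance and ran from untreated cells, at scores from -13.75 to -8.38, to MC18, at 13.09 to 16.53, with MC70 at 1.09 to 2.34 and PB28 at -6.36 to -3.32. The second component carried 17.2%, and on it MC18 replicate 3, at 13.40, stood apart from MC18 replicates 1 and 2, at -10.08 and -9.80. PB28 replicate 1 had the highest score on that component, 14.85. The third component, with 15.3%, placed MC70 at 11.33 to 13.94 and all other arrays at -0.15 or lower.

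**Figure D1:**
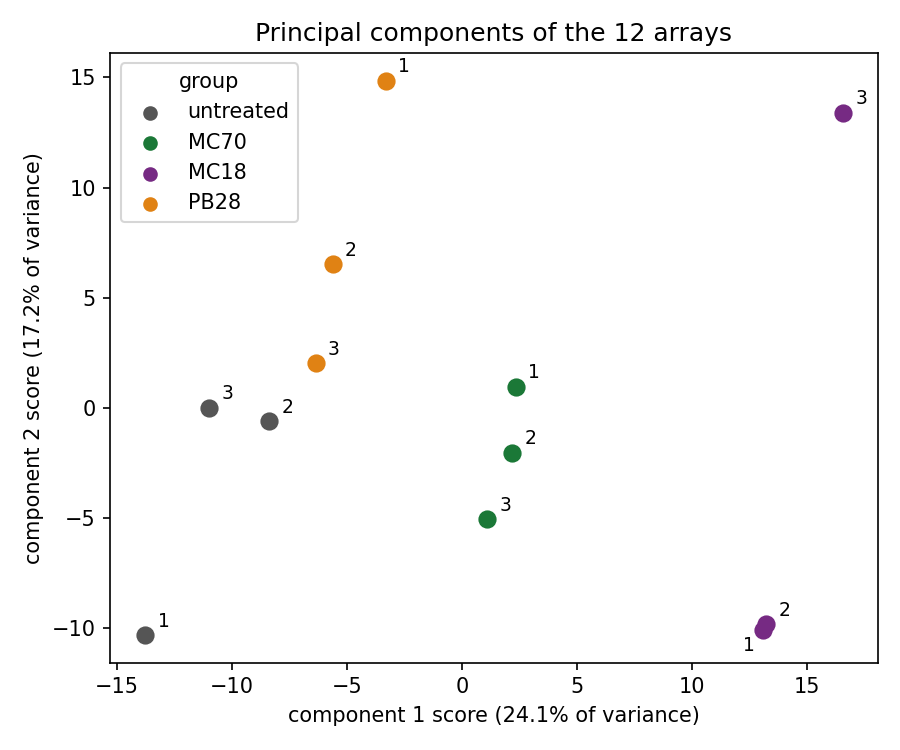
Scores of the 12 arrays on principal components 1 and 2 of 18404 genes, with axes labelled by their percent of variance. Each point is 1 array, coloured by group and numbered by replicate; MC18 replicate 3 lies at 13.40 on component 2 and the other MC18 arrays at -10.08 and -9.80.

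After MC70, some genes of inflammatory signalling and early growth factor responses rose, and some of lipid synthesis fell, against untreated cells. With an estimated correlation their lists did not pass, at adjusted p = 0.0886 for NF-kB and cytokine and for immediate early genes and 0.238 for cholesterol and fatty acid synthesis. PI3, which encodes the protease inhibitor elafin, rose most, from a mean log2 intensity of 7.47 ± 0.15 to 9.21 ± 0.09 (SD, n = 3), 3.34-fold. IL13RA2, a decoy receptor of an interleukin, rose 3.08-fold, ESM1, the secreted proteoglycan endocan, 2.85-fold, and the chemokine gene CCL20 2.81-fold. FGFBP1, a carrier protein of fibroblast growth factors, and NNMT, which methylates nicotinamide, fell most, by 1.06 on the log2 scale each (SE 0.12 and 0.08). The question of this comparison was which transcripts MC70 changes in cells that resist several drugs.

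Of 25 measured NF-kB and cytokine genes, 15 rose and none fell after MC70, 18 rose when adjusted over the list alone, and the mean log2 change was 0.53 (camera adjusted p = 4.11e-20, and adjusted p = 0.0886 with an estimated correlation). Among them were TNFAIP3, an inhibitor of NF-kB signalling, at 1.26 ± 0.10 (log2 change ± SE, adjusted p = 1.40e-05), CXCL2 at 0.99 ± 0.08 (4.12e-05) and IL1B at 1.45 ± 0.15 (1.78e-04). Of 25 immediate early genes and their feedback regulators, 9 rose (12 adjusted over the list alone), with EGR1 at 1.22 ± 0.10, SPRY4 at 0.57 ± 0.06, DUSP6 at 0.57 ± 0.06 and JUNB at 0.71 ± 0.10. The mean change of that list was 0.25 (camera adjusted p = 1.28e-08, and adjusted p = 0.0886 with an estimated correlation). Of 36 genes of cell migration and matrix proteases, 7 rose and the integrin gene ITGB4 fell, its call being lost without MC70 replicate 1 (0.0522). Adjusted over the list alone, 11 rose and 1 fell (mean 0.16, camera adjusted p = 7.08e-07, and adjusted p = 0.0886 with an estimated correlation). The genes that rose included the integrin gene ITGA2 at 0.64 ± 0.07, the urokinase gene PLAU at 0.63 ± 0.08, its receptor PLAUR at 0.47 ± 0.06 and the collagenase gene MMP1 at 0.36 ± 0.06. Outside the lists, the laminin gene LAMB3 rose by 1.20 ± 0.09, NAV3 by 1.21 ± 0.07 and the complement gene C3 by 1.16 ± 0.11.

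Of 21 cholesterol synthesis genes, 6 fell and none rose after MC70, and 12 fell when adjusted over the list alone (mean -0.20, camera adjusted p = 5.67e-07, and adjusted p = 0.238 with an estimated correlation). DHCR7, which catalyses a last step of cholesterol synthesis, changed by -0.43 ± 0.07 (adjusted p = 0.00336). The 6 cholesterol genes became 2 without MC70 replicate 1 or 2, and 1 without MC70 replicate 3 or untreated replicate 1 or 2. Of 14 fatty acid synthesis genes, SCD, FADS2 and FASN fell (5 adjusted over the list alone; mean -0.18, camera adjusted p = 0.00127, and adjusted p = 0.238 with an estimated correlation). The desaturase genes SCD and FADS2 changed by -0.73 ± 0.10 and -0.54 ± 0.09. The call for FASN, at -0.34, was lost without MC70 replicate 1, 2 or 3, MC18 replicate 1, untreated replicate 1, 2 or 3 or PB28 replicate 2 (adjusted p up to 0.152).

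Among stress responses after MC70, 5 of 34 ATF4 target genes rose, with the asparagine synthetase gene ASNS at 0.66 ± 0.10 and VLDLR at 0.38 ± 0.06, and STC2 fell, at -0.49 ± 0.07 (8 and 1 adjusted over the list alone). The rises were 3 without MC70 replicate 2 and 2 without MC70 replicate 3 or untreated replicate 3. The mean change of the ATF4 list was 0.08 (camera adjusted p = 0.0198, adjusted p = 0.615 with an estimated correlation, and 0.134 without untreated replicate 3). Of 25 p53 target genes, 5 rose, on either adjustment, with the cell cycle inhibitor CDKN1A at 0.70 ± 0.12 and the death receptor gene TNFRSF10B at 0.40 ± 0.06; 3 rose without MC70 replicate 1, 2 or 3 or untreated replicate 2, and 2 without untreated replicate 3. That list's mean was 0.10 (camera adjusted p = 0.0426, adjusted p = 0.238 with an estimated correlation, and up to 0.102 without MC70 replicate 2, MC18 replicate 3 or untreated replicate 1). Of 25 hypoxia genes, 4 rose, with the lysyl oxidase gene LOX at 0.99 ± 0.10, and 1 fell. Without MC70 replicate 2, 2 hypoxia genes rose, and none fell without MC70 replicate 2 or 3 or untreated replicate 3. Adjusted over the list alone, 5 rose and 1 fell (mean 0.12, camera adjusted p = 0.00689, and adjusted p = 0.207 with an estimated correlation). Of 23 autophagy genes, MAP1LC3B, OPTN and SQSTM1 rose (5 adjusted over the list alone), MAP1LC3B by 0.51 ± 0.07 (mean 0.09, camera adjusted p = 0.0131, adjusted p = 0.309 with an estimated correlation, and 0.0638 without untreated replicate 1). The calls for OPTN and SQSTM1 were lost with single arrays left out, to adjusted p = 0.0595 for OPTN without MC70 replicate 2 or untreated replicate 1, and to at most 0.0908 for SQSTM1 without MC70 replicate 1, 2 or 3 or untreated replicate 1 or 3. Of 25 genes of the unfolded protein response, SDF2L1 and HERPUD1 fell, 8 when adjusted over the list alone (mean -0.13, camera adjusted p = 6.48e-05, and adjusted p = 0.238 with an estimated correlation); without MC18 replicate 3, 5 fell. Both calls were lost without MC70 replicate 1 or 3 or untreated replicate 1 or 2, to at most 0.0757 for SDF2L1 and 0.115 for HERPUD1, the latter also without MC70 replicate 2.

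Histone and DNA replication genes were lower on average after MC70, with few members past the threshold. Of 39 histone genes, 5 fell (11 lower and 1 higher adjusted over the list alone), with H2BC14 at -0.70 ± 0.11, and the mean was -0.19 (camera adjusted p = 8.99e-07, and adjusted p = 0.372 with an estimated correlation). The 5 histone genes became 1 without MC70 replicate 1 or 2 or untreated replicate 1 or 3, 2 without MC70 replicate 3 or untreated replicate 2, and 8 without PB28 replicate 3. H3C12 and H2AC25, histone genes outside that list, changed by -0.85 ± 0.11 and -0.61 ± 0.09. Small nucleolar RNAs, which like most histone messages lack poly(A) tails, had a mean change of 0.08 in the same comparison (camera adjusted p = 0.0553). Of 46 genes of the G1/S transition and DNA replication, UNG, MCM5 and MCM3 fell and CCNE1 rose (16 lower and 1 higher adjusted over the list alone; mean -0.12, camera adjusted p = 2.45e-06, and adjusted p = 0.372 with an estimated correlation). Without MC18 replicate 3, 9 of these fell, 1 without MC18 replicate 2, PB28 replicate 2, MC70 replicate 3 or untreated replicate 1 or 2, and none without MC70 replicate 1 or 2 or untreated replicate 3. Each of the 4 calls was lost when MC70 replicate 1 or 2 or untreated replicate 3 was left out, and each with further arrays, with adjusted p up to 0.0759 for UNG, 0.142 for MCM5, 0.137 for MCM3 and 0.115 for CCNE1. Of 39 oxidative phosphorylation genes, SDHC fell (3 adjusted over the list alone; mean -0.06, camera adjusted p = 0.015, and adjusted p = 0.63 with an estimated correlation). Of 31 interferon response genes, OASL and BST2 fell and SAMD9 rose (3 and 2 adjusted over the list alone; mean -0.08, camera adjusted p = 0.0362, and adjusted p = 0.379 with an estimated correlation). The call of the first list was lost without MC70 replicate 3 or untreated replicate 2 (up to 0.144). That of the second was lost without MC70 replicate 1, MC70 replicate 2, MC18 replicate 3 or untreated replicate 2 (up to 0.313). Without MC18 replicate 3, 3 oxidative phosphorylation genes fell, and without PB28 replicate 3, 2 fell and 1 rose. OASL was lost without MC70 replicate 1 (0.0502), SDHC without MC70 replicate 1 or 3 or untreated replicate 3 (up to 0.0685). SAMD9 was lost without MC70 replicate 1 or 3 or untreated replicate 1 (up to 0.0782), and BST2 without any 1 of the 6 arrays compared (up to 0.096).

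By limma, 670 genes differed between MC70 and untreated cells, 480 higher and 190 lower, and 79 of them by at least 1.5-fold. For all 670 the 3 arrays of one group lay beyond the 3 of the other, as did 27.8% of all genes, where chance gives 10%. The number of genes fell to 294, 239 and 304 without MC70 replicate 1, 2 and 3, and to 289, 395 and 365 without untreated replicate 1, 2 and 3, and 328 genes were lower without MC18 replicate 3. Of 39 lists, 14 passed with the preset correlation, 7 up and 7 down, and 0 with an estimated one; at an unadjusted p under 0.05, limma gave 3492 genes.

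**Figure D2:**
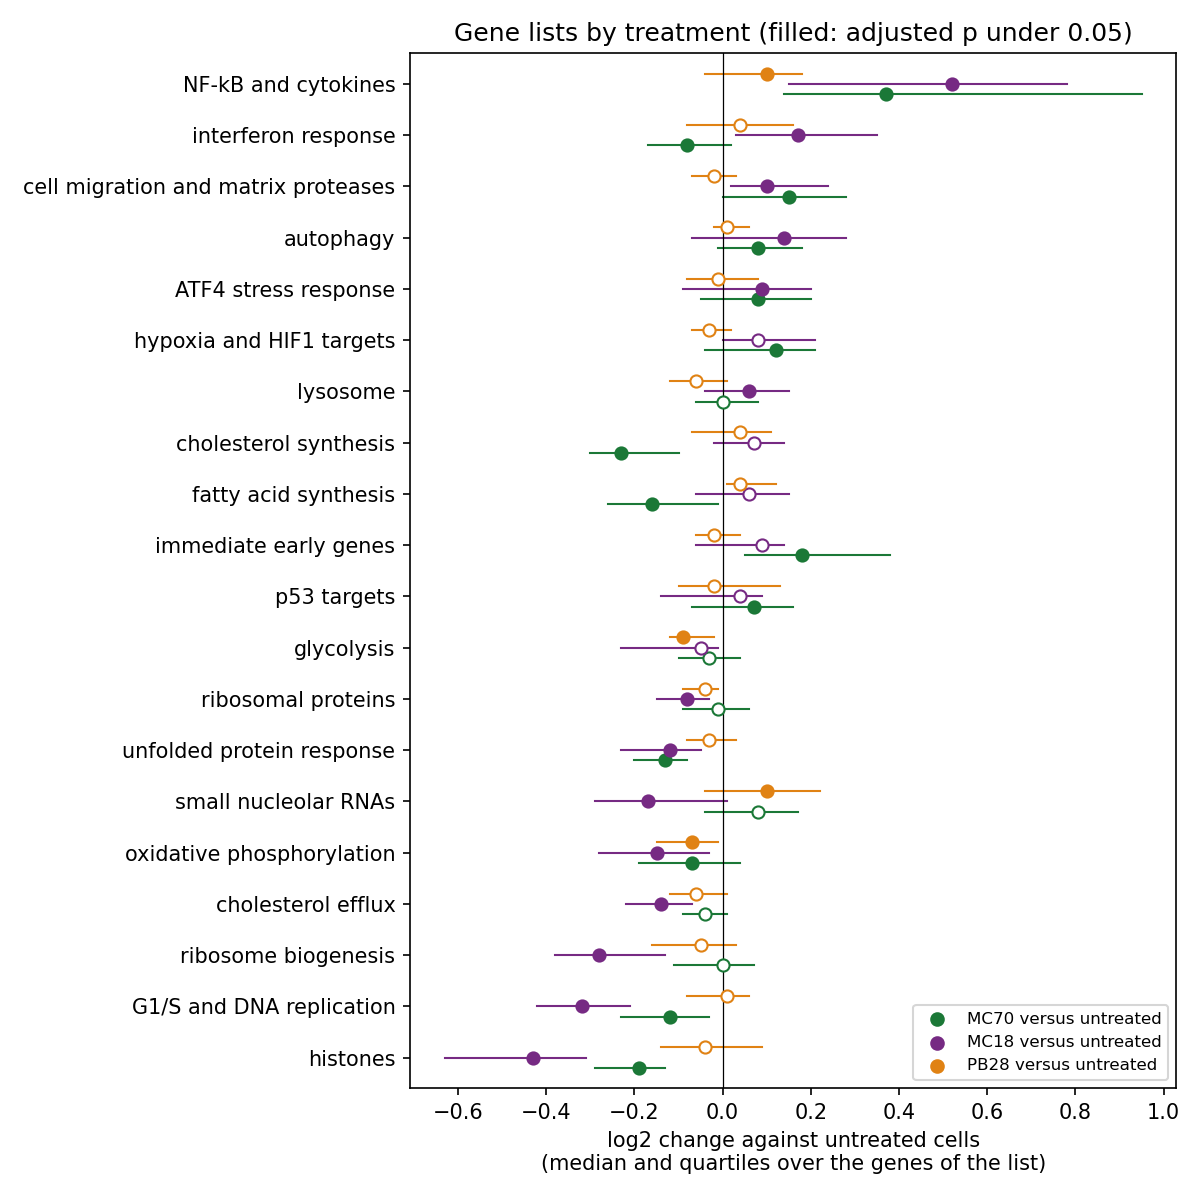
Change of each gene list that passed against untreated cells in at least 1 treatment, as the median (point) and quartiles (line) of the log2 changes of its genes, for MC70, MC18 and PB28. Filled points mark a camera adjusted p under 0.05 with the preset correlation; the median change of NF-kB and cytokine genes was 0.37 after MC70 and 0.52 after MC18, and that of histone genes -0.19 and -0.43.

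After MC18, given at the same stated dose and time as MC70, some cytokine and interferon-induced genes rose, and some genes of DNA replication, histones and ribosome production fell. With an estimated correlation none of the 39 lists passed, and these had adjusted p from 0.103 to 0.129. The complement gene C3 rose most, from 7.87 ± 0.26 to 10.13 ± 0.07 (SD, n = 3), 4.81-fold. IL1A rose 2.71-fold, PI3 2.65-fold and SERPINA1, the gene of alpha-1 antitrypsin, 2.48-fold. The largest falls were in histone genes, led by H2BC14 with a log2 change of -1.19 ± 0.11, and in PCLAF, a partner of the replication clamp, at -0.85 ± 0.09, for which a second probe set gave -0.62. The comparison asks which transcripts MC18 changes in the same cells.

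Of 46 G1/S and DNA replication genes, 31 fell and none rose after MC18 (36 adjusted over the list alone), with a mean of -0.31 (camera adjusted p = 1.60e-17, and adjusted p = 0.129 with an estimated correlation). GINS4, CDC45 and MCM7, parts of the replicative helicase, changed by -0.62 ± 0.06, -0.60 ± 0.07 and -0.46 ± 0.06. UHRF1 was lower at -0.68 ± 0.08, while a second probe set of that gene gave -0.07. Of 39 histone genes, 24 fell (28 adjusted over the list alone; mean -0.48, camera adjusted p = 7.17e-17, and adjusted p = 0.129 with an estimated correlation), among them H3C8 at -1.07 ± 0.10 and H4C2 at -0.86 ± 0.09. Of 24 ribosome biogenesis genes, 15 fell, on either adjustment (mean -0.28, camera adjusted p = 3.30e-10, and adjusted p = 0.103 with an estimated correlation). They included BOP1, which acts in the maturation of ribosomal RNA, at -0.71 ± 0.08, BYSL at -0.48 ± 0.07 and DKC1 at -0.43 ± 0.07. Of 68 small nucleolar RNAs, a class sensitive to how short RNA is recovered, 10 fell and 1 rose in the same comparison (14 and 1 adjusted over the list alone; mean -0.15, camera adjusted p = 6.09e-04, and adjusted p = 0.483 with an estimated correlation). The single rise was lost without MC18 replicate 1 or 2 or untreated replicate 1 or 3, and 2 rose without untreated replicate 2. The falls included SNORD74 at -0.67 ± 0.07 and SNORD30 at -0.62 ± 0.09.

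Of 25 NF-kB and cytokine genes, 17 rose after MC18 and PTGS2, the inducible cyclooxygenase, fell, at -0.53 ± 0.07 (18 and 2 adjusted over the list alone; mean 0.48, camera adjusted p = 3.11e-13, and adjusted p = 0.129 with an estimated correlation). The largest rises among them were IL1A at 1.44 ± 0.12, TNFAIP3 at 1.19 ± 0.10 and IL1B at 1.11 ± 0.15, and SOD2 rose by 0.78 ± 0.08. Of 31 interferon response genes, 11 rose and 2 fell (14 and 3 adjusted over the list alone; mean 0.23, camera adjusted p = 1.44e-06, and adjusted p = 0.103 with an estimated correlation). The sensors of foreign RNA IFIH1 and RIGI rose by 0.74 ± 0.07 and 0.59 ± 0.06, IFIT2 by 0.89 ± 0.09 and DDX60 by 0.79 ± 0.09. Without MC18 replicate 3, 8 interferon genes rose and 1 fell, and without untreated replicate 1, 7 rose. The 2 falls were 1 without MC70 replicate 1, 2 or 3 or untreated replicate 3, and 0 without MC18 replicate 1 or 2 or untreated replicate 1 or 2. Of 36 migration and protease genes, 10 rose and RHOB fell (15 and 1 adjusted over the list alone; mean 0.15, camera adjusted p = 5.25e-05, and adjusted p = 0.103 with an estimated correlation). PLAU rose by 1.10 ± 0.08 and ITGA2 by 0.56 ± 0.07, and without MC18 replicate 3, 2 genes fell. The 10 rises were 6 without MC18 replicate 2 or untreated replicate 1, and 5 without untreated replicate 3.

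Of 23 autophagy genes, 6 rose and none fell after MC18 (8 and 1 adjusted over the list alone; mean 0.14, camera adjusted p = 0.0023, and adjusted p = 0.244 with an estimated correlation). The autophagy receptor genes SQSTM1, OPTN and NBR1 rose by 0.69 ± 0.07, 0.61 ± 0.06 and 0.49 ± 0.08. Of 30 lysosome genes, 5 rose, led by the protease gene CTSB at 0.57 ± 0.06, and CTSL fell, at -0.46 ± 0.07 (6 and 1 adjusted over the list alone). The lysosome list's mean was 0.07 (camera adjusted p = 0.0335, adjusted p = 0.535 with an estimated correlation, and up to 0.0703 without MC18 replicate 3 or untreated replicate 1 or 3); without MC18 replicate 3, 4 rose and 2 fell. Of 34 ATF4 target genes, 9 rose, on either adjustment (mean 0.11, camera adjusted p = 0.00633, and adjusted p = 0.535 with an estimated correlation), with ASNS at 0.74 ± 0.10 and ALDH1L2 at 0.69 ± 0.10; 5 rose without MC18 replicate 2 or untreated replicate 1, and 4 without untreated replicate 3. Of 25 genes of the unfolded protein response, 7 fell, among them SDF2L1 at -0.81 ± 0.08 and the chaperone gene HSPA5 at -0.36 ± 0.06, and CREB3L2 rose. The counts were the same adjusted over the list alone (mean -0.14, camera adjusted p = 0.0023, and adjusted p = 0.364 with an estimated correlation). Of 39 oxidative phosphorylation genes, 11 fell (12 lower and 1 higher adjusted over the list alone; mean -0.15, camera adjusted p = 6.95e-05, and adjusted p = 0.429 with an estimated correlation), with COX8A at -0.83 ± 0.13. Without MC18 replicate 1, 7 of these fell, and 6 without untreated replicate 1 or 2. Of 39 ribosomal protein genes, 6 fell, on either adjustment (mean -0.13, camera adjusted p = 0.00633, and adjusted p = 0.711 with an estimated correlation). Of 8 cholesterol efflux genes, PLTP and LPCAT3 fell, at -0.61 ± 0.08 and -0.32 ± 0.06 (3 adjusted over the list alone; mean -0.18, camera adjusted p = 0.0195, adjusted p = 0.364 with an estimated correlation, and 0.0644 without MC18 replicate 3).

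By limma, 2379 genes differed between MC18 and untreated cells, 1195 higher and 1184 lower, and 172 of them by at least 1.5-fold. For 2362 of them the groups' arrays did not overlap, as for 29.7% of all genes, where chance gives 10%. The number of genes fell to 1355 without untreated replicate 1. The genes lower were 754 without MC18 replicate 2 and 785 without untreated replicate 2, and those higher 743 without untreated replicate 3. Of 39 lists, 14 passed with the preset correlation, 6 up and 8 down, and 0 with an estimated one; at an unadjusted p under 0.05, limma gave 4896 genes.

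After PB28, given at 25 nM and so not at the dose of the other compounds, no single gene passed the threshold against untreated cells. By limma, 0 genes passed, with 1932 genes, 10.5% of those tested, at an unadjusted p under 0.05. The gene with the smallest p among those higher was ZNF429, with a mean of 5.34 ± 0.11 after PB28 and 4.62 ± 0.03 in untreated cells (SD, n = 3, adjusted p = 0.11). It was followed by MIR221 at a log2 difference of 0.62 ± 0.11 (0.292) and by CXCL2, RNU11 and NREP at 0.43, 0.57 and 0.28 (0.372 each). Among those lower, OR51G1 differed by -0.65 ± 0.10 (0.143), CRYGA by -0.45 ± 0.07 and MIR125B1 by -0.41 ± 0.07 (0.161 each), and PRADC1 and PNMA6A by -0.36 and -0.54 (0.372 each). ZNF429, OR51G1, CRYGA and MIR125B1 were low in signal, below the median of every array. The arrays of the groups did not overlap for 17.8% of genes, where chance gives 10%.

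Of the lists, 4 passed after PB28, 2 up and 2 down, and none of their members passed over all genes. The list of 68 small nucleolar RNAs had a mean change of 0.09 (camera adjusted p = 0.00182), the 25 NF-kB and cytokine genes of 0.10 (0.00985), the 39 oxidative phosphorylation genes of -0.07 (0.033) and the 16 glycolysis genes of -0.09 (0.0352). Adjusted over the list alone, 0, 3, 0 and 0 members were higher and 0, 0, 2 and 0 lower. Each of the 4 lists had adjusted p = 0.986 with an estimated correlation. Each call was lost with 1 array left out: small nucleolar RNAs without untreated replicate 1 or PB28 replicate 1 (up to 0.446), and NF-kB and cytokines without untreated replicate 3 or PB28 replicate 2 (up to 0.489). The call for oxidative phosphorylation was lost without untreated replicate 2 or 3 or PB28 replicate 3 (up to 0.71), and glycolysis without untreated replicate 1 or 2 or PB28 replicate 3 (up to 0.339). Without untreated replicate 2, 2 genes passed, and without MC18 replicate 3, 1 did. Without untreated replicate 3, 2 lists passed, 1 each way. The mean change of each of the 4 lists kept its sign with single arrays left out, but which lists passed changed. There were 6 up and 0 down without PB28 replicate 3, 5 up and 0 down without untreated replicate 2, and 1 up and 5 down without PB28 replicate 1.

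MC70 and MC18, compared directly at the same stated dose and time, differed in interferon-induced genes, which were lower after MC70, and in some genes of early growth factor responses, which were higher. IFIT2 had a mean of 7.24 ± 0.04 after MC70 and 8.40 ± 0.04 after MC18 (SD, n = 3), a difference of -1.16 (95% interval -1.36 to -0.95, adjusted p = 4.01e-05). ESM1 was higher after MC70 by 1.79 (1.57 to 2.00), IL13RA2 by 1.48 (1.24 to 1.73), PTGS2 by 1.14 (0.98 to 1.29) and EGR1 by 1.07 (0.85 to 1.29). C3 was lower, with a difference of -1.10 (-1.34 to -0.87), and SERPINA1 and the tight junction gene CLDN16 differed by -1.04 and -1.01. Some genes of lipid synthesis were lower after MC70, and some of ribosome production and DNA replication were higher. With an estimated correlation, adjusted p was 0.197 for immediate early genes and for both lipid lists, 0.07 for ribosome biogenesis and 0.239 for G1/S and DNA replication.

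Of 31 interferon response genes, 9 were lower and none higher after MC70 than after MC18 (14 adjusted over the list alone), with a mean difference of -0.31 (camera adjusted p = 1.34e-11). This list passed with adjusted p = 0.0474 with an estimated correlation, the only one of the 39 to do so in any of the 6 comparisons. IFIT3 differed by -1.06 ± 0.09, DDX60 by -1.03 ± 0.09 and IFIH1 by -0.80 ± 0.07. Of 25 immediate early genes, 7 were higher after MC70 (9 adjusted over the list alone; mean 0.20, camera adjusted p = 9.33e-06, and adjusted p = 0.197 with an estimated correlation). They included FOS at 0.67 ± 0.09, DUSP5 at 0.47 ± 0.08 and DUSP6 at 0.43 ± 0.06. Of 21 cholesterol synthesis genes, 10 were lower after MC70 (11 adjusted over the list alone; mean -0.27, camera adjusted p = 6.08e-10, and adjusted p = 0.197 with an estimated correlation). Among them were MSMO1 at -0.81 ± 0.11, DHCR7 at -0.57 ± 0.07 and IDI1 at -0.41 ± 0.07, and without MC70 replicate 3, 6 were lower. A part of the MSMO1 difference was a rise after MC18 against untreated cells, at 0.38 to 0.56 with single arrays left out. FDPS rose there too and STARD4 fell, and each of these 3 calls was lost with at least 1 array left out. Of 14 fatty acid synthesis genes, 5 were lower (6 adjusted over the list alone; mean -0.24, camera adjusted p = 1.42e-05, and adjusted p = 0.197 with an estimated correlation), with FADS2 at -0.93 ± 0.09 and SCD at -0.62 ± 0.10. These 5 became 2 without MC70 replicate 2 and 3 without MC70 replicate 3 or MC18 replicate 1 or 2.

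Of 24 ribosome biogenesis genes, 11 were higher after MC70 than after MC18 (17 adjusted over the list alone; mean 0.27, camera adjusted p = 2.59e-12, and adjusted p = 0.07 with an estimated correlation), with BOP1 at 0.53 ± 0.08 and BYSL at 0.48 ± 0.07. The number was 6 without MC70 replicate 1 or MC18 replicate 2, and 5 without MC70 replicate 2 or 3. Of 46 G1/S and DNA replication genes, 11 were higher (19 adjusted over the list alone; mean 0.20, camera adjusted p = 2.18e-10, and adjusted p = 0.239 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was at 0.85 ± 0.12 and CDC45 at 0.37 ± 0.07, and 17 genes were higher without MC18 replicate 3, 5 without MC70 replicate 1, 7 without MC70 replicate 2 and 6 without MC18 replicate 2. Of 39 histone genes, 9 were higher (16 adjusted over the list alone; mean 0.29, camera adjusted p = 1.63e-10, and adjusted p = 0.239 with an estimated correlation). Of 68 small nucleolar RNAs, 7 were higher alongside them (15 adjusted over the list alone; mean 0.23, camera adjusted p = 1.64e-10, and adjusted p = 0.198 with an estimated correlation). Without PB28 replicate 3, 14 histone genes were higher, and without MC70 replicate 1 or MC18 replicate 2, 4 small nucleolar RNAs were. Lists with a mean difference of 0.13 or less in size also passed: those of mitosis (47 genes, 1 higher), ribosomal proteins (39, 5 higher), metallothioneins (11, 1 lower), lysosome (30, 1 higher and 4 lower) and oxidative phosphorylation (39, 1 higher). The mitosis gene UBE2C was lost without MC70 replicate 1, 2 or 3, MC18 replicate 1, 2 or 3 or untreated replicate 1. There were 6 other mitosis genes higher without MC18 replicate 3, and without PB28 replicate 3 the number was 3. The 5 ribosomal protein genes became 0 without MC70 replicate 2, 1 without MC18 replicate 1 or 2, and 2 without MC70 replicate 1 or 3, and without MC70 replicate 1 there was 1 lower. The metallothionein was lost without any 1 array other than MC18 replicate 3 and PB28 replicates 2 and 3, and 2 lysosome genes were lower without MC70 replicate 2 or 3. The oxidative phosphorylation gene NDUFB8 was lost without MC70 replicate 1, 2 or 3 or MC18 replicate 2 or 3. There were 2 other genes of that list higher without MC18 replicate 3, and without PB28 replicate 2 or 3 the number was 2. Adjusted over the list alone, 0, 5, 0, 1 and 0 members were higher and 0, 0, 3, 6 and 0 lower in these. Their camera adjusted p were 0.00812, 0.0118, 0.0127, 0.0182 and 0.0238, with adjusted p = 0.59, 0.59, 0.404, 0.527 and 0.553 with an estimated correlation. Each of these calls was lost with 1 array left out: mitosis without MC18 replicate 1 or 2 (up to 0.141), ribosomal proteins without MC70 replicate 2 (0.076), and metallothioneins without MC70 replicate 1 or MC18 replicate 2 (up to 0.0631). The call for lysosome was lost without MC70 replicate 1 or MC18 replicate 3 (up to 0.0631), and that for oxidative phosphorylation without MC70 replicate 2 or MC18 replicate 1 or 2 (up to 0.158).

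The NF-kB and cytokine list did not pass between MC70 and MC18 (mean difference 0.05, camera adjusted p = 0.651, and adjusted p = 0.898 with an estimated correlation), with 4 members higher and 4 lower after MC70 (8 and 5 adjusted over the list alone). PTGS2 and IL11 were higher after MC70, IL11 by 0.77 ± 0.11, and CCL5, SOD2 and IL6 were higher after MC18, at -0.97 ± 0.11, -0.67 ± 0.08 and -0.66 ± 0.10. For TNFAIP3, which rose after each compound against untreated cells, the direct difference did not pass. By limma, 1120 genes differed between MC70 and MC18, 643 higher and 477 lower after MC70, and 96 of them by at least 1.5-fold. The number fell to 636, 538 and 556 without MC70 replicate 1, 2 and 3, and to 728 and 631 without MC18 replicate 1 and 2. At an unadjusted p under 0.05, limma gave 3756 genes. The arrays did not overlap for 1119 of the 1120 genes and for 25.8% of all genes, where chance gives 10%.

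**Figure D3:**
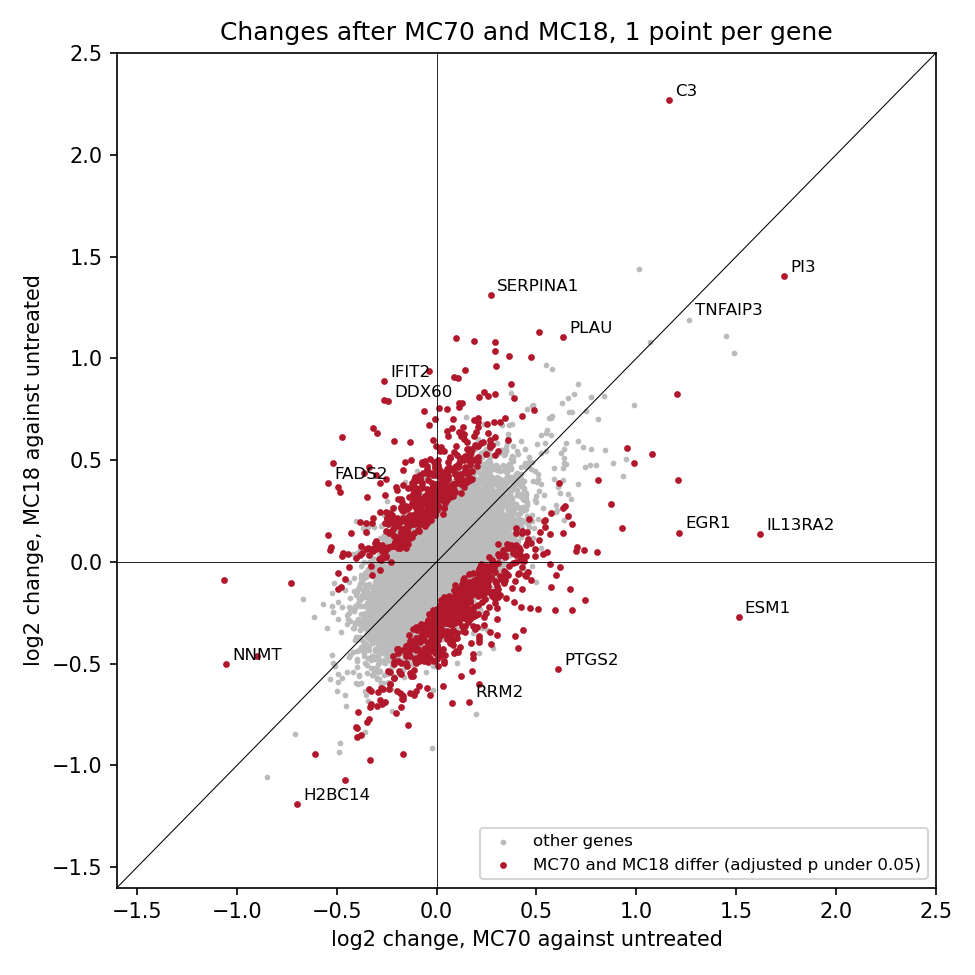
Log2 change of each of 18404 genes after MC70 (horizontal) and after MC18 (vertical), both against untreated cells, with the diagonal of equal change. Red points are the 1120 genes that differ between MC70 and MC18 at an adjusted p under 0.05; ESM1, IL13RA2 and EGR1 lie far to the right of the diagonal, and C3, IFIT2 and SERPINA1 above it.

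Most changes that MC70 and MC18 shared ran in the same direction. Of the genes past the threshold in both comparisons with untreated cells, 235 were higher after both compounds and 107 were lower after both. Shared controls push such overlaps up, so no expected number is given. PI3, TNFAIP3, IL1B and C3 were among those higher after both, and H2BC14 and H3C12 among those lower. Another 11 genes passed in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.56, beside a simulated 0.50 for unchanged groups measured against shared controls, with a covariance of 0.0169 against a simulated 0.0046. For MC70 and PB28 r was 0.43 with a covariance of 0.0084, and for MC18 and PB28 it was 0.48 with 0.0115. Without MC18 replicate 3, r for MC70 and MC18 was 0.506, and without untreated replicate 2 it was 0.623, the ends of its range over single arrays left out. The simulated value was made for 3 arrays in each group, so it is no reference for these fits. The same 3 untreated arrays entered each comparison and are too few to be divided between them.

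The same MC70 and MC18 arrays were also compared with PB28, with stated doses that differ. MC70 was higher than PB28 by 1.58 ± 0.09 for PI3, 1.58 ± 0.10 for ESM1, 1.45 ± 0.11 for IL13RA2, 1.31 ± 0.09 for LAMB3 and 1.16 ± 0.10 for TNFAIP3. FGFBP1 differed by -1.26 ± 0.12 and PLAC8 by -0.90 ± 0.10. Of 25 NF-kB and cytokine genes 13 were higher after MC70 (15 adjusted over the list alone; mean 0.43, camera adjusted p = 7.25e-15, and adjusted p = 0.122 with an estimated correlation). Of 25 immediate early genes 9 were higher (11 adjusted over the list alone; mean 0.25, camera adjusted p = 6.61e-10, and adjusted p = 0.0909 with an estimated correlation). Of 21 cholesterol synthesis genes 8 were lower (10 adjusted over the list alone; mean -0.25, camera adjusted p = 7.64e-10, and adjusted p = 0.134 with an estimated correlation), and 5 without MC70 replicate 2 or 3 or PB28 replicate 2. In all, 652 genes differed, 466 higher and 186 lower, 64 by at least 1.5-fold, and 12 of 39 lists passed, none with an estimated correlation. The number of genes was 327, 214 and 233 without MC70 replicate 1, 2 and 3, 350, 281 and 330 without PB28 replicate 1, 2 and 3, and 1008 without MC18 replicate 3. At an unadjusted p under 0.05, limma gave 3359 genes, and the arrays of 26.0% of all genes did not overlap, where chance gives 10%.

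MC18 was higher than PB28 by 1.98 ± 0.11 for C3, 1.25 ± 0.09 for PI3, 1.11 ± 0.09 for SERPINA1 and 1.10 ± 0.08 for PLAU, and lower for H2BC14 at -1.35 ± 0.11 and PCLAF at -0.97 ± 0.09. Of 46 G1/S and DNA replication genes 29 were lower after MC18 (34 adjusted over the list alone; mean -0.31, camera adjusted p = 2.66e-23, and adjusted p = 0.0997 with an estimated correlation). Of 39 histone genes 22 were lower (31 adjusted over the list alone; mean -0.46, camera adjusted p = 3.26e-22, and adjusted p = 0.0997 with an estimated correlation). Of 68 small nucleolar RNAs 16 were lower with them (33 lower and 2 higher adjusted over the list alone; mean -0.24, camera adjusted p = 5.12e-11, and adjusted p = 0.153 with an estimated correlation). The 29 G1/S genes became 18 without MC18 replicate 1 and 15 without MC18 replicate 2. The histone genes became 13 without MC18 replicate 1 or PB28 replicate 1, 14 without MC18 replicate 2 and 12 without PB28 replicate 2, and the small nucleolar RNAs 9, 7 and 8 without MC18 replicate 1, MC18 replicate 2 and PB28 replicate 1. Without MC18 replicate 3 and PB28 replicate 1 together, 13 histone genes and 13 small nucleolar RNAs were lower. Of 31 interferon response genes 9 were higher after MC18 (12 higher and 3 lower adjusted over the list alone; mean 0.18, camera adjusted p = 3.43e-05, and adjusted p = 0.119 with an estimated correlation). Fibroblast markers, a list meant to show other cell types, had a mean of -0.11 with no member past the threshold (camera adjusted p = 0.0466, and adjusted p = 0.189 with an estimated correlation). That call was lost without MC18 replicate 1 or 3, untreated replicate 3 or PB28 replicate 1, 2 or 3 (up to 0.102), while 2 of its members were lower without MC18 replicate 3 and 1 without MC18 replicate 1. In all, 1380 genes differed, 710 higher and 670 lower, 121 by at least 1.5-fold, and 16 of 39 lists passed, none with an estimated correlation. The number of genes was 604 and 584 without MC18 replicate 1 and 2, and 785 and 634 without PB28 replicate 1 and 2. Without MC18 replicate 3, 794 were higher and 1226 lower, and without PB28 replicate 3, 423 were higher and 561 lower. At an unadjusted p under 0.05, limma gave 3966 genes, and the arrays of 23.9% of all genes did not overlap, where chance gives 10%.

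The multidrug transporter genes ABCB1, ABCC1 and ABCG2 did not pass against untreated cells. ABCB1, the gene of P-glycoprotein, was near the top of the scale, with 12.32 ± 0.03 in untreated cells, 12.47 ± 0.07 after MC70, 12.34 ± 0.03 after MC18 and 12.34 ± 0.06 after PB28 (SD, n = 3). Its log2 difference from untreated cells was 0.15 after MC70 (95% interval 0.02 to 0.28, adjusted p = 0.202), 0.02 after MC18 (-0.11 to 0.15, 0.859) and 0.02 after PB28 (-0.11 to 0.16, 0.916), and MC70 differed from MC18 by 0.13 (adjusted p = 0.258). ABCC1 differed from untreated cells by 0.17 after MC70 (0.168), 0.13 after MC18 (0.203) and -0.09 after PB28 (0.627). Between MC70 and PB28 it passed, at 0.26 (adjusted p = 0.0442), a call that was lost without any 1 array other than MC18 replicate 3 (up to 0.168). ABCG2 was low, with 5.82 ± 0.05 in untreated cells, and differed by 0.15 (0.371), 0.07 (0.679) and 0.02 (0.953). TMEM97, the sigma 2 receptor gene, differed by -0.17 after MC70 (0.256), -0.16 after MC18 (0.215) and 0.07 after PB28 (0.766), and between MC70 and MC18 by -0.01 (-0.18 to 0.15). Of 15 multidrug transporter genes, none passed after MC70 and 3 rose after MC18, on either adjustment: ABCA3, a lipid transporter, by 0.70 ± 0.08 (adjusted p = 1.59e-04), ABCA2 and ABCB4. The calls for ABCB4, at 0.28, and ABCA2, at 0.31, were lost with single arrays left out, ABCB4 without MC18 replicate 2 or untreated replicate 2 or 3 (up to 0.0932) and ABCA2 without MC18 replicate 1 or 2 or untreated replicate 1 or 3 (up to 0.106). The transporter list had a mean change of 0.02 after MC70 (camera adjusted p = 0.664, and adjusted p = 0.84 with an estimated correlation) and 0.07 after MC18 (0.254, and adjusted p = 0.535 with an estimated correlation). ABCA3 was lower after MC70 than after MC18, with a difference of -0.71 ± 0.08 (2.54e-04).

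**Figure D4:**
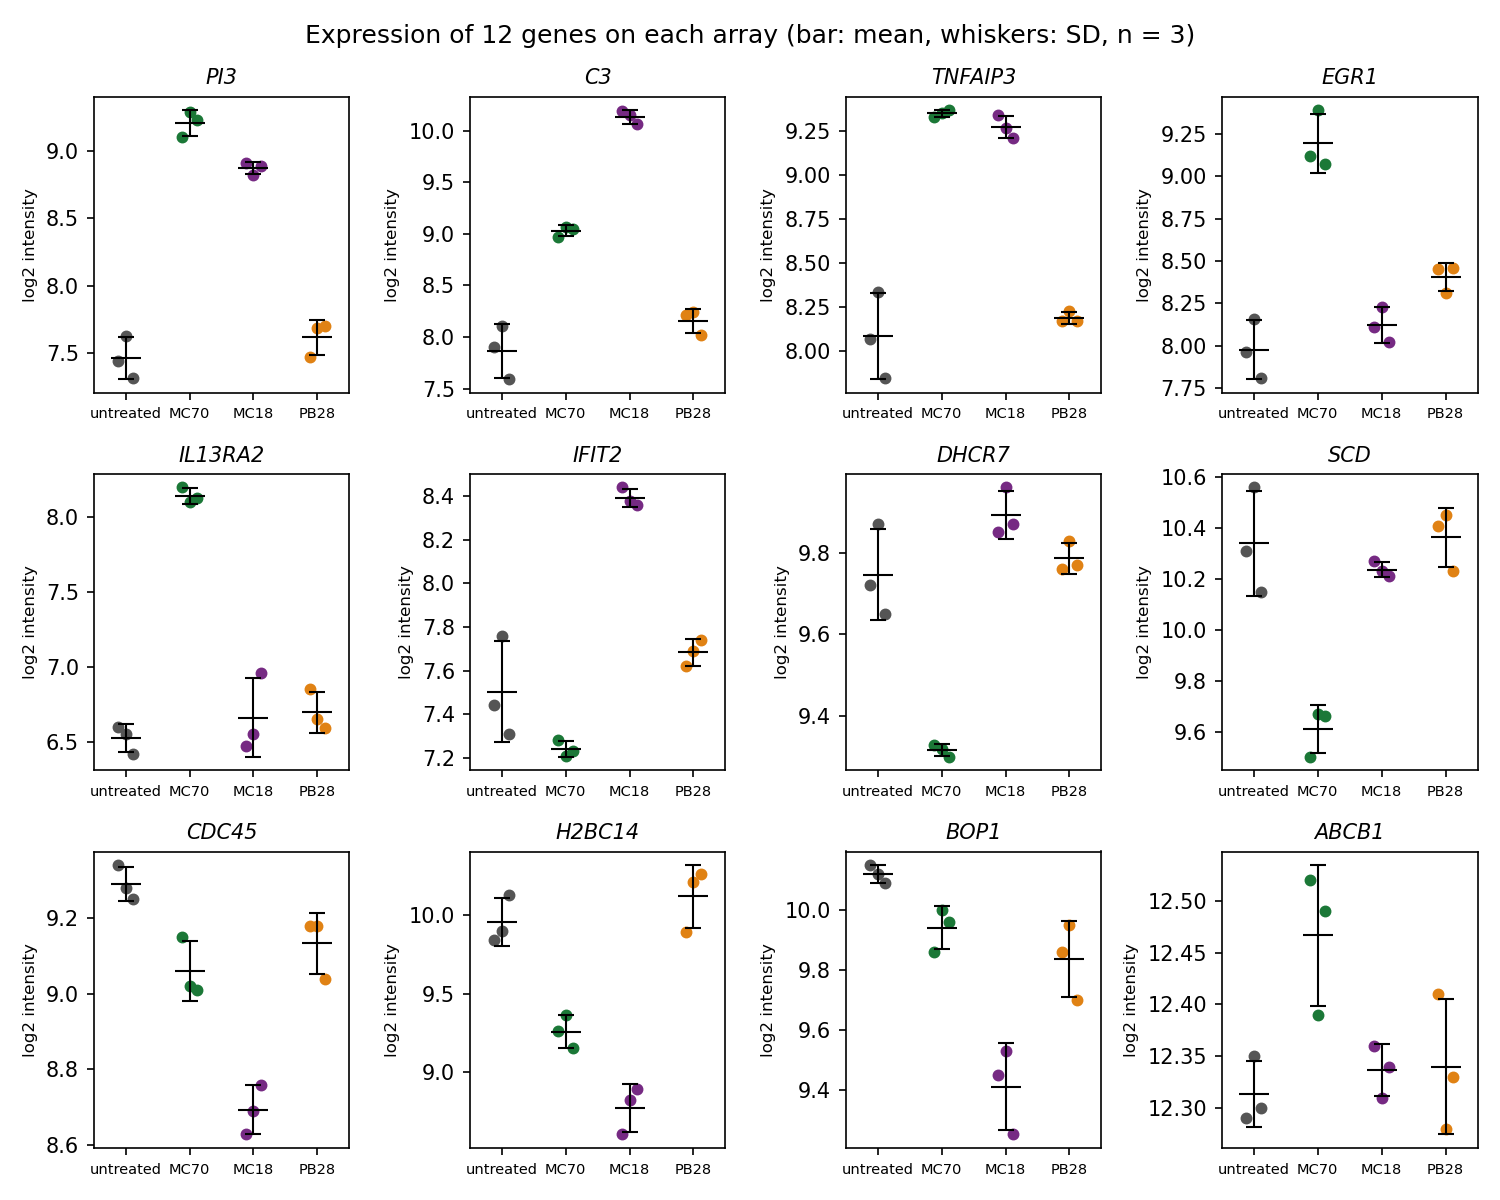
Log2 intensity of 12 genes on each of the 12 arrays, 1 panel per gene, with a point per array, a bar at the group mean and whiskers of 1 SD (n = 3); each panel has its own vertical scale. PI3 and TNFAIP3 are higher after MC70 and MC18, IFIT2 after MC18 and IL13RA2 and EGR1 after MC70, while the group means of ABCB1 lie between 12.32 and 12.47.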

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

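The tests on G1/S and ribosome biogenesis genes, on the interferon list, on a mislabelled array and on leukocyte and endothelial markers alone were chosen after the results were seen, while the splits of the arrays, the small nucleolar RNA covariate and the joint test of the marker lists were planned. A first rule picked out results that passed against untreated cells in opposite directions after MC70 and MC18. It picked 11 genes. Their direct difference follows from this choice, and its size is given without a test. MC70 minus MC18 was 1.14 for PTGS2, 0.91 for HBEGF, an epidermal growth factor receptor ligand, 0.83 for RBP4, 0.75 for ADAMTS6, 0.66 for POLR3G and 0.65 for CRABP2. It was -1.01 for CLDN16, -0.93 for FADS2, -0.86 for STC2, -0.83 for OASL and -0.46 for PLEKHA2. The same rule picked the interferon response list, at a mean of -0.31. A second rule asked whether measured probe sets outside the gene tests also changed. Of the 13917 probe sets outside those tests, which include further sets of tested genes, 89 passed for MC70 against untreated cells, 494 for MC18 and 1 for PB28.

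MC18 replicate 3 lay apart from the other MC18 arrays on the second principal component, and its difference from them had an SD of 0.217 and 0.213, against 0.149 between those arrays. A mislabelled array of another group was argued against: over 2205 genes that changed in the other MC18 arrays, the slope of replicate 3 on their change was 0.83, and the highest slope of an MC70 or PB28 array was 0.43. The recovery of short RNA was argued against by a small nucleolar RNA mean only 0.03 higher than in the other MC18 arrays. RNA of leukocytes or endothelial cells did not show as higher markers, with list means of -0.14 ± 0.04 and -0.16 ± 0.05 relative to those arrays (SE over genes). Low values were lower on replicate 3 in general, with a lower quartile over all probe sets of 4.355 against 4.448 and 4.426. Many of these markers were low in signal, so a small addition of such RNA could be hidden and is not excluded. RNA of fibroblasts stays open: their list had the highest mean, -0.005 ± 0.08, but its members went both ways, with LUM at 0.66 and COL1A1 at -0.30. Its mitosis and G1/S lists were 0.15 and 0.14 higher. Housekeeping, ribosome biogenesis and oxidative phosphorylation genes were higher too, by 0.10, 0.09 and 0.08, while cholesterol efflux and estrogen response genes were lower, at -0.11 and -0.10. The upper quartile of replicate 3 was 8.085 against 8.053 and 8.047, so its values were spread more widely at both ends. Whether this spread accounts for the list differences was not tested, and the cell cycle lists do not single out culture timing. The handling or timing of that culture stays open, as the labels give neither.

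Interferon-induced genes were lower after MC70 than after MC18, with a list mean of -0.31 ± 0.03 (SE). The pattern did not rest on MC18 replicate 3, without which the mean was -0.31 ± 0.03. Relative to 100 genes of like signal per list gene, the list mean was -0.33 ± 0.03. The authors' quantile normalization already holds genes of like signal alike between arrays, so a value near -0.31 was to be had whatever the cause. Whether that normalization adds to the difference therefore stays open. Array means of the list were 6.90 to 6.92 after MC70 and 7.22 to 7.23 after MC18, with untreated cells at 6.95 to 7.06, nearer to MC70. Against untreated cells the fall after MC70 was small, at -0.10 to -0.04 with single arrays left out. Its camera call was lost without MC70 replicate 1 or 2, MC18 replicate 3 or untreated replicate 2. The rise after MC18, at 0.21 to 0.27, kept its call throughout, so opposite directions are not firmly shown. A different action of the compounds on interferon signalling may explain this, as an untested hypothesis, and culture conditions shared by a group's arrays stay open.

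The histone, G1/S and ribosome biogenesis genes that passed after MC18 were all lower, and of 68 small nucleolar RNAs 10 fell and 1 rose with them. None of these lists passed with an estimated correlation, at adjusted p = 0.129, 0.129, 0.103 and 0.483. If histone messages without poly(A) tails were only recovered less well, their difference should end once small nucleolar RNAs were accounted for. With the array mean of that list as a covariate, the histone mean moved from -0.48 ± 0.08 to -0.35 ± 0.09, with a slope of 0.86 ± 0.38. The covariate was itself lower on the MC18 arrays, at 6.96 to 7.01, than on all others, at 7.05 or more. It is also an indirect and noisy measure of recovery, which can leave a remainder whatever the cause. The test therefore cannot tell whether recovery accounts for none, a part or all of the histone fall. G1/S genes at -0.31 ± 0.04 and ribosome biogenesis genes at -0.28 ± 0.03 have poly(A) tails and were lower too. These lists were taken up after their fall was seen, and it does not show how histone messages were recovered. The mitosis list did not pass alongside (mean -0.04, camera adjusted p = 0.573), and the cause of these falls stays open. Cell numbers or cycle phases were not analysed here.

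The arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 670, 2379, 0, 1120, 652 and 1380 genes for MC70, MC18 and PB28 against untreated cells, MC70 against MC18, MC70 against PB28 and MC18 against PB28. The highest other split gave 1, 0, 0, 0, 0 and 2 genes, and counts as large came in 1, 1, 10, 1, 1 and 1 of 10 splits. For gene lists the real split gave 14, 14, 4, 13, 12 and 16, the highest other 11, 11, 15, 9, 13 and 13, and counts as large came in 1, 1, 8, 1, 3 and 1. Mixed splits passed up to 15 lists while calling at most 2 genes. Each mixed split keeps a part of the treatment difference, which can pass lists, and that difference raises the spread within groups, which holds down gene counts. A kept part does not account for PB28 against untreated cells, where mixed splits passed up to 15 lists and the real one 4. Nor does it readily account for MC70 against PB28, at 13 against 12. These values argue that lists there passed on a structure of the samples, other than treatment, that the preset correlation does not cover. For the other comparisons the splits cannot tell treatment from such a structure. The list results stay weaker than their adjusted p, as at most 1 list per comparison passed with an estimated correlation. Across all 4 groups 2415 genes differed, against at most 38 in the other drawn splits. Only the real split of 100 reached it, the smallest share these draws can give, so an arbitrary grouping of the arrays is unlikely to give it. Conditions shared by a group's cultures were not told apart from treatment there.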

How the results depend on the processing

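All alternatives were planned except the fit without both arrays that stood apart and the counts of list members with arrays left out, which were added after the result was seen. Over all settings, 91 counts of changed genes stayed within 1.5-fold of the value reported and 47 moved, and for lists passing 100 stayed and 8 moved. Of 314 called pairs of a named gene and a comparison, 229 were called under every alternative fit, the minimum of 1.5-fold not counted, and 0 reversed. In the order MC70, MC18 and PB28 against untreated cells, MC70 against MC18, MC70 against PB28 and MC18 against PB28, leaving out 1 array gave 239 to 976, 1355 to 2479, 0 to 2, 538 to 1234, 214 to 1008 and 584 to 2020 genes. The lists passing were then 12 to 15, 13 to 17, 2 to 6, 10 to 14, 11 to 13 and 12 to 16. Without the 30% of genes with the lowest signal, the counts for MC70 rose to 1085 against untreated cells and 1040 against PB28, with fewer genes to adjust over. With all probe sets they were 422 and 391, with 1 for PB28 against untreated cells, over more tests. With only the groups compared, which leaves fewer arrays to estimate the variance, MC18 against untreated cells gave 1276, MC70 against MC18 636, and MC70 and MC18 against PB28 370 and 452. An intensity trend with robust moderation gave 1129, 1692 and 1129 for MC70 against untreated cells, MC18 and PB28. Array weights, of which MC18 replicate 3 had 0.30, gave 1234, 5, 2264, 1827 and 3385 for MC70 and PB28 against untreated cells, MC70 against MC18, and MC70 and MC18 against PB28. A minimum of 1.5-fold left 79, 172, 96, 64 and 121, the median change of called genes being smaller. With an estimated correlation 0, 0, 0, 1, 0 and 0 lists passed in the order above, and with fry 0 for PB28 against untreated cells. Replicate number as a block gave 488, 1981, 0, 910, 464 and 1088 genes, and the numbers did not pair the arrays. Centring on array medians raised the share of called genes that were higher after MC70 from 71.6% to 80.9% against untreated cells.

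Among the named genes and the lists that passed, signs changed only for single genes that had not passed. Lists that had not passed were not checked for a change of sign. ABCB1 turned to -0.001 for MC18 and -0.002 for PB28 against untreated cells after quantile normalization, for PB28 also to -0.007 with weights and to -0.011 without PB28 replicate 1 or without both arrays. For MC18 against PB28 it turned to 0.000 after quantile normalization, 0.006 centred, 0.018 with weights, 0.014 without MC18 replicate 2, 0.033 without PB28 replicate 1 and 0.031 without both. TMEM97 in MC70 against MC18 turned to 0.003 centred, 0.028 with weights, 0.034 without MC70 replicate 2 and 0.064 without MC18 replicate 3 or both, and ABCC1 there to -0.004 with weights and -0.013 without MC18 replicate 3 or both. ABCG2 turned to -0.025 for PB28 against untreated cells without PB28 replicate 1 or both, and to -0.013 for MC18 against PB28 without PB28 replicate 3. Over all leave-outs ABCB1 lay between -0.011 and 0.052 for PB28 against untreated cells and between -0.030 and 0.033 for MC18 against PB28. TMEM97 and ABCC1 lay between -0.069 and 0.064 and between -0.013 and 0.069 for MC70 against MC18, and ABCG2 reached 0.080 for PB28 against untreated cells and 0.092 for MC18 against PB28. Their cause was not tested beyond the values lying near 0. In simulations with 200 of 18404 genes changed after MC70 only, 0.1% of changes of 0.25 were recovered. This is no rate for the real comparisons, where more genes passed and some smaller changes did too, as for PLEKHA2 at 0.21 after MC18.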

Other observations

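Some single genes of lists that did not pass changed, chosen here after their values were seen. After MC70, the aldo-keto reductase genes AKR1C1 and AKR1C3 rose by 0.52 ± 0.07 and 0.54 ± 0.08 (log2, SE), and CYP1B1, a target of the aryl hydrocarbon receptor, changed by -0.44 ± 0.06. AKR1C1 and CYP1B1 also differed between MC70 and MC18, at 0.37 and -0.41 (adjusted p = 0.0078 and 0.00239). The lists of oxidative stress response and aryl hydrocarbon receptor targets passed in no comparison, with smallest camera adjusted p of 0.187 and 0.117. CD68, a lysosomal membrane protein best known from macrophages, rose by 0.58 ± 0.08 after MC70, while the leukocyte list did not pass (0.489). The collagen chaperone gene SERPINH1 fell after both compounds, at -0.53 and -0.57. After MC18, the glycolysis gene HK2 and the vasodilator gene ADM fell, at -0.49 ± 0.10 and -0.64 ± 0.08, and the receptor genes EGFR and INSR rose by 0.45 ± 0.07 and 0.43 ± 0.08.

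A pair of cell cycle inhibitor genes differed between the compounds, while their list of 16 passed in no comparison. CDKN1A was higher after MC70 than after MC18 by 0.63 ± 0.12 (adjusted p = 0.00672), while RBL2, a repressor of cell cycle genes, was lower, at -0.54 ± 0.06 (3.54e-04). Among genes of epithelial mesenchymal transition, SNAI1 was higher after MC70 than after MC18 by 0.42 ± 0.08, and FN1 was lower, at -0.39 ± 0.06. The urokinase receptor gene PLAUR was higher after MC70 by 0.56 ± 0.06, and its ligand PLAU lower, at -0.47 ± 0.08. Of the 7 measured sigma receptor genes and partners, PGRMC2 was lower after MC70 than after MC18, at -0.39 ± 0.07 (0.00664), and ANK2 and ITPR3 rose after MC18 by 0.31 and 0.32, with no pass of the list (smallest camera adjusted p 0.0857).

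In all, 16 lists passed in no comparison. Apart from those above they were multidrug transporters (smallest camera adjusted p 0.0693), pregnane X receptor targets (0.182), heat shock (0.053), cell cycle inhibitors (0.668), cyclin D and MYC (0.454), and apoptosis (0.428). The others were epithelial mesenchymal markers (0.112), epithelial markers (0.269), estrogen response (0.205), targets of PI3K and FOXO (0.108), housekeeping (0.498) and endothelial markers (0.124). The list of mitochondrially encoded genes had 0 measured members.

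A transcriptional rise or fall of ABCB1 was not found by these tests, and its interval after MC70, 0.02 to 0.28 on the log2 scale, is not corrected for the number of genes. The activity of the transporter, doxorubicin and protein levels were not analysed here.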
